A study of Mus musculus with 6 samples.

How the data were processed

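Gene expression was measured by RNA sequencing in 6 libraries of mouse bone marrow blasts carrying MLL-AF9, 3 from chemotherapy-sensitive and 3 from chemotherapy-resistant blasts. Total RNA was extracted with a column kit and libraries were made with a TruSeq RNA kit, per the labels' protocols, and the series' design text names an Illumina HiSeq instrument. The authors deposited counts per Ensembl gene as whole numbers, with no normalisation apparent in the values. The submitters' processing notes name TopHat2 and RSEM and the mouse build mm9, without versions or roles. The annotation release, the strand setting, the treatment of shared reads, read length and trimming are not given in the sources used here, nor whether the whole numbers are direct counts or rounded RSEM estimates. Genes with near-identical copies, overlapping genes and antisense pairs are therefore uncertain. All 6 columns of the deposited count table matched 1 sample each by title, and 0 columns were left unused.

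The table held 35932 genes, of which 13569 were at 0 in every library. Totals per library were 28980058, 25129812 and 30695602 counts in sensitive and 31856009, 22206341 and 26217850 counts in resistant blasts. The 20 most abundant genes took 6.62% to 7.25% of a library. Gene IDs were matched to symbols with the GENCODE M21 annotation, a later build than the authors used, which served for names, each gene's chromosome, transcript lengths and 3′ UTR sequence only; 31636 IDs matched, 12993 of them among the tested genes. No coordinates are given, since no annotation of the authors' build was used here.

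Counts were filtered with filterByExpr, scaled with TMM factors (0.9784 to 1.0164) and tested in edgeR 4.0.16 under R 4.3.3 with the quasi-likelihood F test (glmQLFit and glmQLFTest, design with the group alone), with Benjamini-Hochberg adjustment over 13414 genes and a threshold of 0.05. Values per gene are TMM-normalised CPM, as mean ± SD over 3 libraries; log2 fold changes are resistant over sensitive, ± SE. The common dispersion of 0.007 corresponds to a coefficient of variation of 8.4% between libraries of a group. Pairs of libraries within a group had a chi-square per degree of freedom of 3.92 to 13.59 over genes with a mean of at least 20 counts, and pairs between groups 37.47 to 63.21, so no library was a second copy of another. Intervals of count ratios and floors cover counting error only.

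In all, 41 gene lists were fixed before the data were examined, on drug handling, DNA damage, cell cycle, apoptosis, the MLL-AF9 program, myeloid maturation, immunity, metabolism, stress, RNA handling and other marrow cell types. Lists with at least 5 tested members (40 of 41) were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists. With the correlation estimated from the data, camera passed 0 of the 40 lists (2 at an unadjusted p under 0.05, and fry passed 20), and the 8 lists called with the preset value each had an adjusted p = 0.698. The adjustment gave this same value to lists not called with the preset value, such as megakaryocyte and platelet markers. It is therefore not particular to any list. With an estimated correlation camera also takes its degrees of freedom from the 6 libraries rather than from the genes, which lowers its power. Camera compares a list with the other genes; fry, run as an alternative, asks whether a list's own genes move on balance one way. Member counts come from the test over all genes, and again with p-values adjusted over the list alone.

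The named genes were set by a rule fixed at the same time. It took a panel of 14 genes of drug response and MLL-AF9 leukemia; the 10 largest rises and 10 largest falls among genes past the test, with groups that did not overlap, a mean of at least 50 counts, and no unnamed models, antigen receptor segments or histone cluster genes; and up to 4 members with the smallest adjusted p from each list with at least 3 members past the test or a camera call. Some genes that the rule names are not reported here. Genes outside the rule are said to be so where they are named.

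The edgeR step was tested on simulated data made from the means and library sizes of this comparison, in 10 simulations of 13414 genes with 200 changed. With dispersions on the fitted trend, 68.2% of genes changed 1.5-fold, 83.3% of those changed 2-fold and 96.4% of those changed 4-fold were recovered, and 3.8% of calls were false. With gene-wise dispersions the shares were 66.4%, 81.5% and 95.2%, and 7.6% of calls were false, above the nominal 5%. The data themselves gave 5260 calls, far more than the 200 genes changed here. The shares recovered and false depend on that number and need not hold for the data.

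Alternatives were other scalings (RLE, upper quartile, library totals), DESeq2 1.42.0, limma-voom, no low-count filter or a CPM filter, the replicate number as a block, each library left out in turn, other cell type genes left out, an estimated correlation, fry, another prior count, a fold-change minimum and a stricter threshold. Removal of transcript length and GC trends before camera was added after seeing the data.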

Results

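RNA sequencing measured gene expression in mouse bone marrow blasts, the immature cells of an acute myeloid leukemia driven by MLL-AF9, a fusion of the Mll1 (Kmt2a) and Af9 (Mllt3) genes. The 6 libraries fell into 2 groups of 3. Sensitive blasts carried the label of vehicle treatment, and resistant blasts that of cytarabine with doxorubicin, a nucleoside analog and an anthracycline that are given together as chemotherapy. The label of resistance and the drug exposure therefore went together in all 6 libraries, and the labels do not give the dose, the time of harvest or whether replicates came from separate animals. The p-values below thus measure the spread between these libraries, which may be technical. Library totals ranged from 22206341 to 31856009 counts, and 17825 to 18654 genes had at least 1 count. A floor of 3 counts corresponded to 0.0942 to 0.135 CPM (counts scaled to a common library total), and this floor covers counting error only.

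The series asks how the transcriptome of blasts that resist chemotherapy differs from that of sensitive blasts. Resistant blasts expressed more mRNA of the protein synthesis and respiratory machinery, with 41 of 49 cytosolic ribosomal protein genes higher and 8 not passing, and 23 of 44 oxidative phosphorylation genes higher and 21 not passing. They expressed less of the genes of neutrophil and monocyte maturation, with 15 of 22 neutrophil maturation genes and 17 of 22 monocyte genes lower. Each of these 4 lists passed camera with its preset correlation, and each had an adjusted p = 0.698 with an estimated correlation. In the same libraries the 4 globin genes, markers of red cells, went from a sum of 57.2 ± 15.5 to 0.651 ± 0.61 CPM. The drug efflux pump gene Abcg2 rose 3.58-fold, from 8.09 ± 0.59 to 29 ± 1.2 CPM (SD, n = 3 per group). Its list, anthracycline efflux and metabolism genes, had 5 of 17 members higher and 5 lower (camera adjusted p = 0.861). Of 13414 genes tested, 2475 were higher and 2785 lower in resistant blasts at an adjusted p of 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment), and of these 409 rose and 636 fell by more than 2-fold. The median size of the change among these 5260 genes was 0.42 on the log2 scale. The 3 values of one group lay apart from the 3 of the other in 7029 genes (52.4%), against 10% by chance. The first principal component held 65.7% of the variance and placed the sensitive libraries at -40.8 to -34 and the resistant ones at 33.8 to 40.4. Without sensitive library 2, the count of higher genes dropped to 1641.

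**Figure D1:**
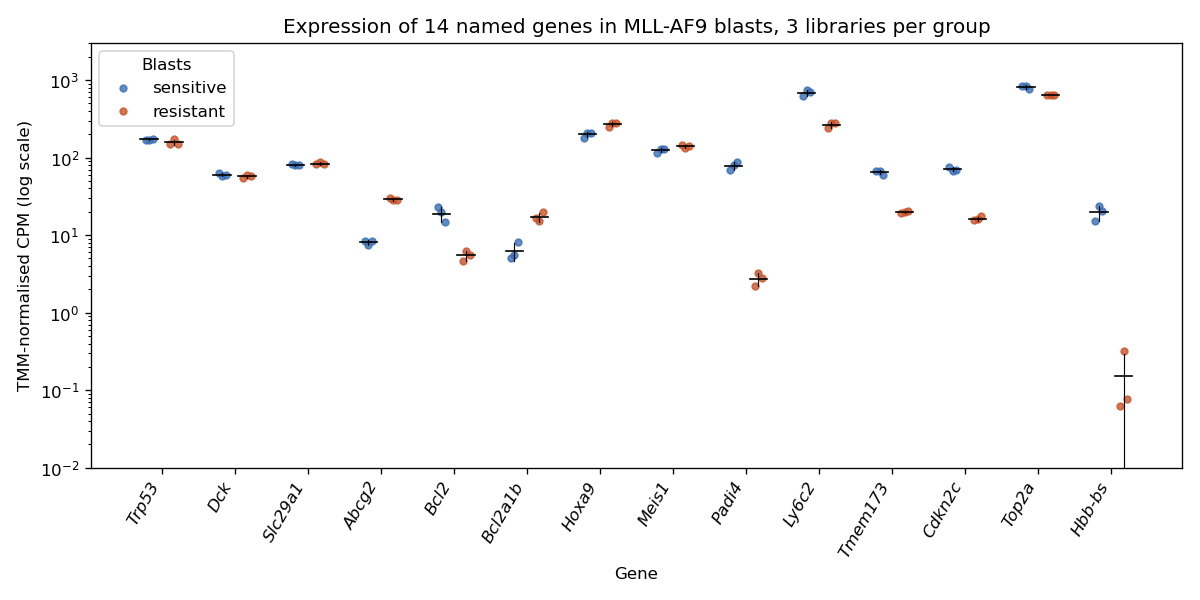
Each point is 1 library's expression of a named gene, in TMM-normalised CPM on a log axis, with sensitive blasts in blue and resistant blasts in orange; horizontal bars are means of 3 libraries and vertical lines are 1 SD. Padi4 lies near 78.6 CPM in sensitive and 2.74 CPM in resistant blasts, while the values of Dck, Slc29a1 and Trp53 lie close together in both groups.

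Most genes that carry and activate cytarabine did not pass the test. Dck, the kinase that makes the first phosphorylation of cytarabine, was at 60.2 ± 2.24 CPM in sensitive and 57.1 ± 2.65 CPM in resistant blasts (log2 fold change -0.08 ± 0.06 SE, adjusted p = 0.367, edgeR quasi-likelihood). The nucleoside transporter gene Slc29a1 (0.05 ± 0.06, adjusted p = 0.545) and Samhd1, which encodes a hydrolase of cytarabine triphosphate (-0.07 ± 0.07, adjusted p = 0.503), did not pass the same edgeR test either. Of 19 tested cytarabine uptake and metabolism genes, 2 were higher, 1 was lower and 16 did not pass. Adjusted over the list alone, 2 were higher and 0 lower (camera adjusted p = 0.531). With fry the list passed as higher (adjusted p = 0.0413; highest over 20 alternatives 0.707). The higher genes were Nme2, a nucleoside diphosphate kinase (0.59 ± 0.05), and the nucleotidase gene Nt5c2 (0.32 ± 0.06). The lower gene was Tk1 (-0.18 ± 0.06, edgeR adjusted p = 0.0401), whose call was lost under 5 of 15 alternatives with adjusted p up to 0.148, among them the fits without sensitive library 2, sensitive library 3, resistant library 1 or resistant library 2.

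Anthracycline efflux and metabolism genes moved in both directions, with 5 of 17 higher, 5 lower and 7 not passing, and the same numbers when adjusted over the list alone (camera adjusted p = 0.861). Abcg2 rose by 1.84 ± 0.09 on the log2 scale (edgeR adjusted p = 2.98e-07). Nqo1, a quinone reductase gene, had a log2 fold change of -3.99 ± 0.43, from 1.27 to 0.0749 CPM, the latter from only 6 counts in sum. Xdh, which encodes xanthine dehydrogenase, fell from 4.57 ± 1.2 to 1.02 ± 0.0498 CPM. Top2a, the topoisomerase gene whose product doxorubicin acts on, fell from 811 ± 49.2 to 641 ± 6.71 CPM (-0.34 ± 0.05, edgeR adjusted p = 0.000732). The efflux pump gene Abcb1a had 0 counts in all 6 libraries, and its paralog Abcb1b was near 1 CPM in both groups (-0.59 ± 0.32, edgeR adjusted p = 0.171); how the counting treated reads shared by this pair is not given.

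Genes of the p53 response did not pass as a group: 6 of 26 were higher, 5 lower and 15 not passing, and the numbers adjusted over the list alone were 6 and 5 (camera adjusted p = 0.515). Trp53 itself had a log2 fold change of -0.13 ± 0.06 (edgeR adjusted p = 0.116) and the cell cycle inhibitor gene Cdkn1a one of 0.12 ± 0.10 (adjusted p = 0.335). Among p53 targets, Pmaip1, which encodes the pro-apoptotic NOXA, rose from 63.7 ± 4.91 to 106 ± 7.71 CPM, while Xpc, a nucleotide excision repair gene (-0.55 ± 0.05), and Btg2, an antiproliferative gene (-0.95 ± 0.13), fell. Bcl2, the anti-apoptotic founder of its family, fell 3.48-fold from 18.9 ± 4.09 to 5.47 ± 0.842 CPM (edgeR adjusted p = 2.65e-05). In the same family Bcl2a1b rose from 6.26 ± 1.65 to 17.2 ± 2.33 CPM, with the reservation that it has near-identical copies, and Mcl1 did not pass (0.18 ± 0.08, adjusted p = 0.0857). Of 9 pro-survival genes 2 were higher, 1 lower and 6 not passing (2 and 1 adjusted over the list alone, camera adjusted p = 0.689). Of 11 pro-apoptotic genes 3 were higher, 3 lower and 5 not passing (3 and 3 adjusted over the list alone, camera adjusted p = 0.886). Bmf, a pro-apoptotic BH3-only gene, fell by 0.88 ± 0.17. In the fit without resistant library 2, Trp53 and Mcl1 passed the edgeR test, with adjusted p = 0.02 and 0.0179. Over 15 alternatives their adjusted p reached 0.302 and 0.266, and Mcl1 also passed without a low-count filter (0.0488).

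Genes downstream of MLL-AF9 split by gene. Hoxa9, a homeobox gene of the MLL-AF9 list, rose from 199 ± 16.4 to 269 ± 16.7 CPM (0.44 ± 0.07, edgeR adjusted p = 0.00088). Hoxa7 (0.62 ± 0.08) and Jmjd1c (0.95 ± 0.06), a histone demethylase family gene, rose too. Bcl2 was among the 3 that fell. In all, 9 of 22 genes were higher, 3 lower and 10 not passing, with 11 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.225). The list's median was 0.20 and camera's direction higher, while its mean was -0.20. With fry the list passed as lower (adjusted p = 0.0413; highest over 20 alternatives 0.698). Meis1, the cofactor of Hoxa9, had a log2 fold change of 0.16 ± 0.06 (edgeR adjusted p = 0.0671). It passed without resistant library 2 (0.0326; highest over 15 alternatives 0.216). Kmt2a fell by 0.22 ± 0.07 (edgeR adjusted p = 0.0265), and Mllt3 was at -0.12 ± 0.08 (0.279); whether reads of the fusion gene were counted toward them is not given. The call of Kmt2a was lost without sensitive library 2, sensitive library 3, resistant library 2 or resistant library 3, with adjusted p up to 0.132 over 15 alternatives. Of 14 hematopoietic stem cell genes 2 were higher, 4 lower and 8 not passing, also when adjusted over the list alone (camera adjusted p = 0.723). Cd34, a progenitor surface marker, rose by 0.30 ± 0.07, and the receptor tyrosine kinase gene Kit fell by 0.31 ± 0.06.

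Neutrophil maturation and monocyte genes were lower in resistant blasts, while the eosinophil granule genes Prg2 and Prg3, given below, rose. Neutrophil maturation genes had a median log2 fold change of -1.40, with 1 of 22 higher, 15 lower and 6 not passing (1 and 16 adjusted over the list alone). Padi4, whose product citrullinates histones in neutrophils, fell 29.2-fold from 78.6 ± 9.18 to 2.74 ± 0.513 CPM, and the lysozyme gene Lyz2 fell from 68.4 ± 12.4 to 18.1 ± 3.06 CPM. Monocyte genes had a median of -0.51, with 3 of 22 higher, 17 lower and 2 not passing (3 and 17 adjusted over the list alone). Ly6c2, the inflammatory monocyte antigen, fell from 681 ± 60.1 to 264 ± 21.3 CPM, and the transcription factor gene Klf2 rose from 4.18 ± 0.294 to 10.2 ± 0.635 CPM. The camera adjusted p was 1.45e-06 for the neutrophil list and 0.00249 for the monocyte list; each had an adjusted p = 0.698 with an estimated correlation. Of 16 primary granule genes, which mark the promyelocyte stage, 3 were higher, 5 lower and 8 not passing (3 and 6 adjusted over the list alone, camera adjusted p = 0.287). Elane, neutrophil elastase, fell from 503 ± 75.1 to 255 ± 50.5 CPM, and Hdc, the histamine-forming enzyme gene, rose from 388 ± 18.7 to 882 ± 132 CPM. Globin transcripts, which mark red cells, moved with these genes: the 4 globin genes together made up 57.2 ± 15.5 CPM in sensitive and 0.651 ± 0.61 CPM in resistant libraries. The other 7 erythroid markers tested had a median log2 fold change of -0.47, with members changed both ways.

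Adhesion and homing genes of the marrow niche were lower, with 2 of 19 higher, 12 lower and 5 not passing, the same numbers when adjusted over the list alone, and a median of -0.49 (camera adjusted p = 0.00267). The list had an adjusted p = 0.698 with an estimated correlation. The adhesion gene Pecam1 fell from 154 ± 19.9 to 47.7 ± 4.46 CPM, and Cd93 from 158 ± 10.3 to 54.1 ± 0.638 CPM. The integrin gene Itgb3 fell by 2.08 ± 0.14. Globin transcripts were lower in the same libraries, as given above for the maturation genes.

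Several immune gene groups held more lower than higher members without passing camera. Among all 13414 tested genes 39.2% changed, with 2475 higher and 2785 lower, so changed members alone do not set a list apart. For MHC class II genes, 1 of 9 was higher, 6 lower and 2 not passing (1 and 6 adjusted over the list alone, camera adjusted p = 0.0768), with H2-Oa at -1.04 ± 0.10. For MHC class I genes 0 of 13 were higher, 5 lower and 8 not passing (0 and 5 adjusted over the list alone, camera adjusted p = 0.0768). H2-T23 fell by 0.68 ± 0.09, and reads of the H2-Q family can be shared between members. Both MHC lists passed camera without resistant library 2 (adjusted p = 0.0459 for class II and 0.0172 for class I). Class II also passed without sensitive library 1 (0.0488) and class I without sensitive library 3 (0.0266). No low-count filter also brought both past the threshold (0.0233 for class II and 0.0204 for class I), as did limma-voom for class I (0.0441) and fry for class II (0.00723). Over 20 alternatives their adjusted p reached 0.698 and 0.773. Tmem173, encoding the cytosolic DNA-sensing adaptor STING, fell from 64.6 ± 3.66 to 20 ± 0.384 CPM, and the DNA sensor gene Cgas fell by 0.39 ± 0.07, whereas the inflammatory caspase gene Casp1 rose by 0.37 ± 0.07. Of 16 DNA-sensing and innate receptor genes 2 were higher, 7 lower and 7 not passing (3 and 7 adjusted over the list alone, camera adjusted p = 0.225). Immune checkpoint and suppressor genes had 3 of 15 higher, 6 lower and 6 not passing (3 and 7 adjusted over the list alone, camera adjusted p = 0.492), with the checkpoint gene Vsir at -0.80 ± 0.06 and the inhibitory receptor gene Pirb at -1.69 ± 0.18. Interferon-stimulated genes had 3 of 30 higher, 6 lower and 21 not passing (3 and 5 adjusted over the list alone, camera adjusted p = 0.723). Mx1 fell by 0.76 ± 0.16 and Oas2 rose by 0.68 ± 0.10. Without sensitive library 1 or resistant library 1, camera's direction for the interferon list turned to higher (adjusted p = 0.928 and 0.601). NF-kB and inflammatory genes had 2 of 17 higher, 5 lower and 10 not passing, also when adjusted over the list alone (camera adjusted p = 0.287), among them the inhibitor gene Nfkbie at -0.66 ± 0.10 and Birc3 at 0.37 ± 0.07. The DNA-sensing and checkpoint lists passed fry as lower (adjusted p = 0.00729 and 0.0132; highest over 20 alternatives 0.698 for each).

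**Figure D2:**
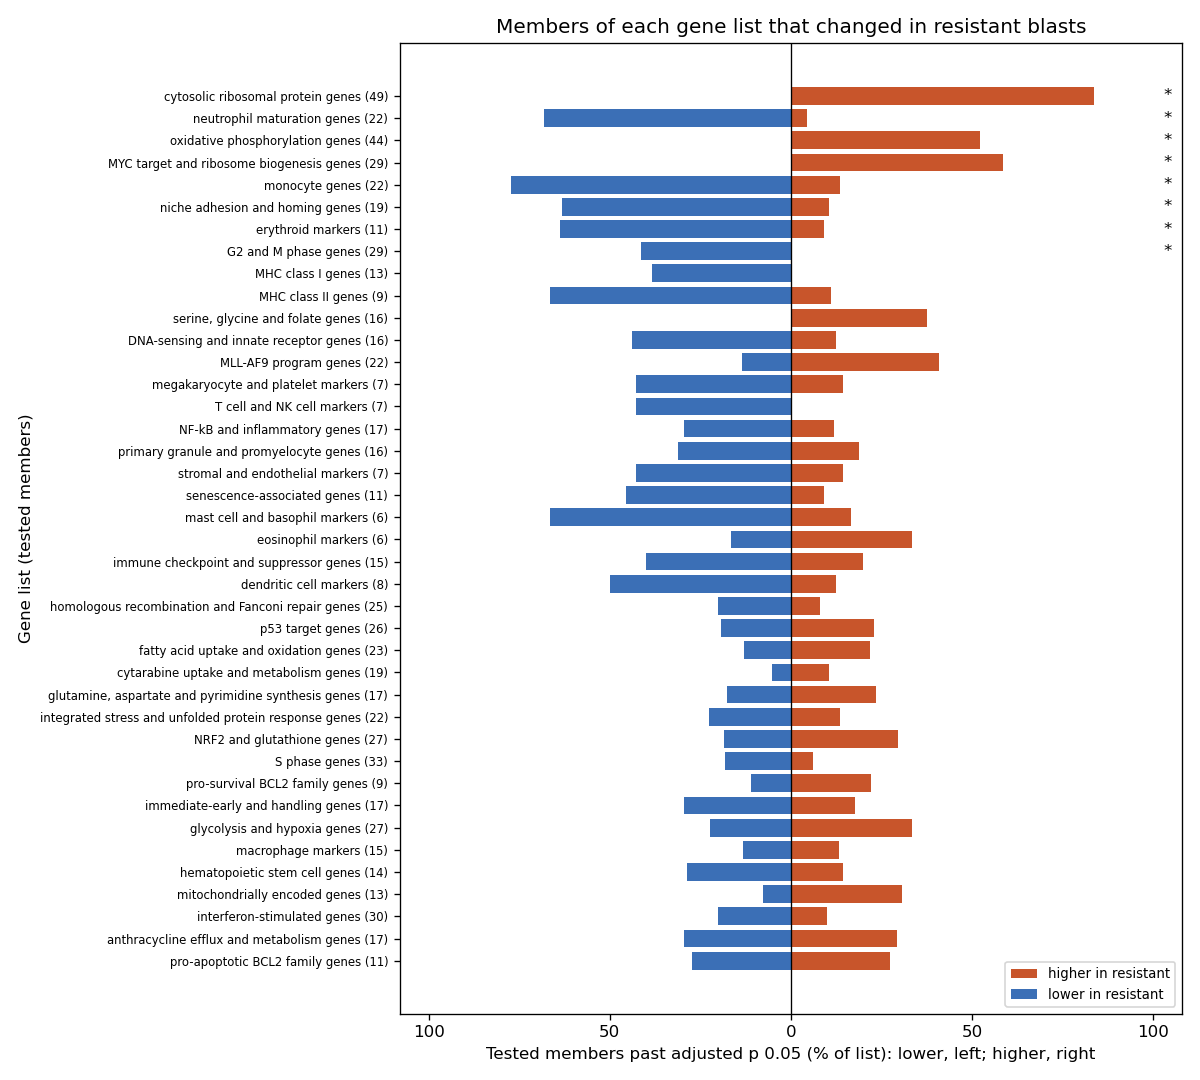
Bars give the percent of each list's tested members that were higher (orange, right) or lower (blue, left) in resistant blasts at an adjusted p of 0.05 in the edgeR test, with the number of tested members in brackets and an asterisk where camera passed with its preset correlation. Among the 40 lists, 3 passed as higher and 5 as lower, and 41 of 49 cytosolic ribosomal protein genes were higher. With an estimated correlation 0 of the 40 lists passed.

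Genes of protein synthesis and respiration rose by small amounts in many members. Of 49 cytosolic ribosomal protein genes, 41 were higher, 0 lower and 8 not passing (44 and 0 adjusted over the list alone), with a median of 0.20. Rpl30 rose from 407 ± 8.05 to 492 ± 14.4 CPM and Rps6 from 747 ± 28.1 to 917 ± 61.9 CPM. Ribosomal protein genes have many pseudogenes that can share their reads. Of 44 oxidative phosphorylation genes 23 were higher, 0 lower and 21 not passing (26 and 0 adjusted over the list alone), with a median of 0.17. Atp5c1, an ATP synthase subunit gene, rose by 0.41 ± 0.05 and Sdhd, a subunit gene of respiratory complex II, by 0.32 ± 0.05. Of 29 MYC target and ribosome biogenesis genes 17 were higher, 0 lower and 12 not passing (17 and 0 adjusted over the list alone), with a median of 0.23. Odc1, the polyamine synthesis enzyme gene, rose by 0.46 ± 0.06, and the nucleolar protein gene Nop58 by 0.38 ± 0.05. Camera adjusted p-values were 5.6e-08, 4.21e-06 and 1.96e-05 for these 3 lists; each had an adjusted p = 0.698 with an estimated correlation. The 4 globin genes were lower in the same resistant libraries (0.651 ± 0.61 against 57.2 ± 15.5 CPM).

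Other metabolic groups did not pass camera. Glycolysis and hypoxia genes had 9 of 27 higher, 6 lower and 12 not passing (9 and 7 adjusted over the list alone, adjusted p = 0.723). The glycolytic genes Ldha (0.56 ± 0.04), Eno1 (0.46 ± 0.05) and Tpi1 (0.43 ± 0.05) rose, and Pfkfb3, a regulator of the pathway, fell by 0.62 ± 0.08. The direction of that list turned to lower without resistant library 2 (adjusted p = 0.732). Serine, glycine and folate genes had 6 of 16 higher, 0 lower and 10 not passing, also when adjusted over the list alone (adjusted p = 0.112). Psph, the last enzyme gene of serine synthesis, rose by 0.58 ± 0.08. That list passed camera without sensitive library 1 (0.0345) and passed fry (0.0308; highest over 20 alternatives 0.698). Fatty acid uptake and oxidation genes had 5 of 23 higher, 3 lower and 15 not passing, also when adjusted over the list alone (adjusted p = 0.515), with Hadh at 0.43 ± 0.07 and the fatty acid transporter gene Slc27a1 at -0.49 ± 0.09. Glutamine, aspartate and pyrimidine synthesis genes had 4 of 17 higher, 3 lower and 10 not passing (4 and 4 adjusted over the list alone, adjusted p = 0.549), with the mitochondrial aspartate-glutamate carrier gene Slc25a12 at -0.63 ± 0.06. NRF2 and glutathione genes had 8 of 27 higher, 5 lower and 14 not passing, also when adjusted over the list alone (adjusted p = 0.549). The mitochondrial superoxide dismutase gene Sod2 rose by 0.54 ± 0.05, and the glutathione reductase gene Gsr fell by 0.54 ± 0.06. Integrated stress and unfolded protein response genes had 3 of 22 higher, 5 lower and 14 not passing, also when adjusted over the list alone (adjusted p = 0.549). The endoplasmic reticulum chaperone gene Hsp90b1 fell by 0.34 ± 0.06.

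Mitotic genes were slightly lower, with 0 of 29 G2 and M phase genes higher, 12 lower and 17 not passing (0 and 13 adjusted over the list alone), a median of -0.12 and a camera adjusted p of 0.0118. This call had an adjusted p = 0.698 with an estimated correlation, the highest over 20 alternatives, and was lost without sensitive library 2 (0.0541) or resistant library 2 (0.0788). Kif11, a spindle motor gene, fell from 269 ± 13.3 to 175 ± 9.34 CPM, and the spindle checkpoint gene Bub1b from 194 ± 4.61 to 141 ± 1.73 CPM. S phase genes had 2 of 33 higher, 6 lower and 25 not passing (1 and 4 adjusted over the list alone, camera adjusted p = 0.58), with the transcription factor genes E2f1 (-0.35 ± 0.07) and E2f2 (-0.47 ± 0.09) lower. The direction of the list turned to higher without resistant library 1 (adjusted p = 0.959). Homologous recombination and Fanconi repair genes had 2 of 25 higher, 5 lower and 18 not passing, also when adjusted over the list alone (camera adjusted p = 0.515). Rad54l, which acts in strand exchange, fell from 73.9 ± 2.61 to 41 ± 4.67 CPM. Senescence-associated genes had 1 of 11 higher, 5 lower and 5 not passing, also when adjusted over the list alone (camera adjusted p = 0.355). The CDK inhibitor gene Cdkn2c fell 4.32-fold from 70.5 ± 4.37 to 16.4 ± 0.962 CPM, while Cdkn2a rose by 0.58 ± 0.12. The senescence list passed fry as lower (adjusted p = 0.00372; highest over 20 alternatives 0.698). Globin transcripts were lower in the libraries with the lower mitotic genes, as given above.

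The largest rises among genes with a mean of at least 50 counts and groups that did not overlap were those of Npr3, Svep1, Tktl1, Shtn1, Sh3pxd2b, Npas3, Gata3, Asgr2, Adgre4 and Pax6, with log2 fold changes from 5.54 down to 3.17. Npr3 encodes the natriuretic peptide clearance receptor and rose from 0.0812 ± 0.0139 to 3.99 ± 0.522 CPM. Its sensitive value rests on 7 counts in sum and lies below the floor of 3 counts per library, so the size of this rise is uncertain. Tktl1, a transketolase-like gene, rose from 1.02 ± 0.502 to 23.8 ± 1.19 CPM, Gata3, a transcription factor gene of T cells and other lineages, from 0.975 ± 0.389 to 12.7 ± 1.28 CPM, and Adgre4, an adhesion receptor gene of myeloid cells, from 3.71 ± 1.03 to 34.1 ± 0.847 CPM. The largest falls included those of Tcf19, Myef2, Hbb-bs, Zcchc3, Nol4, Hbb-bt, Hba-a1, Hba-a2 and Klra17. Nol4, a nucleolar protein gene, fell from 51.1 ± 0.866 to 0.409 ± 0.31 CPM and Myef2, a transcriptional repressor gene, from 17.9 ± 3.47 to 0.09 ± 0.0489 CPM. Resistant libraries held only 3 counts each in sum of Tcf19 and Zcchc3, against 799 and 492 in sensitive ones. The ratio was 252 for Tcf19 (95% exact binomial interval for counting error 86 to 1230) and 155 for Zcchc3 (52.8 to 755). Each of these genes had an edgeR adjusted p of 4.02e-05 or lower. The pairs Hba-a1 and Hba-a2, and Hbb-bs and Hbb-bt, are near-identical, so the split of reads within a pair is uncertain.

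Among markers of other marrow cells, the erythroid list was lower in resistant blasts. Erythroid markers had 1 of 11 higher, 7 lower and 3 not passing, also when adjusted over the list alone, with a median of -4.57 (camera adjusted p = 0.00727) and an adjusted p = 0.698 with an estimated correlation. Hbb-bs fell from 19.7 ± 4.3 to 0.153 ± 0.143 CPM. None of the following marker lists passed camera, and their numbers adjusted over the list alone equal those over all genes unless given. Megakaryocyte and platelet markers had 1 of 7 higher, 3 lower and 3 not passing (adjusted p = 0.225). T cell and NK cell markers had 0 of 7 higher, 3 lower and 4 not passing (0.287), with Bcl11b, a T cell transcription factor gene, falling from 17.9 ± 1.1 to 4.6 ± 2.3 CPM. Stromal and endothelial markers had 1 of 7 higher, 3 lower and 3 not passing (0.355). Mast cell and basophil markers had 1 of 6 higher, 4 lower and 1 not passing (0.419); the mast cell carboxypeptidase gene Cpa3 fell from 30.6 ± 8.63 to 6.88 ± 0.843 CPM. Eosinophil markers had 2 of 6 higher, 1 lower and 3 not passing (0.419); the granule protein genes Prg2 and Prg3 rose from 71.8 ± 22.1 to 301 ± 51.8 and from 41.6 ± 4.14 to 166 ± 30 CPM. Dendritic cell markers had 1 of 8 higher, 4 lower and 3 not passing (0.511), with the integrin gene Itgax falling from 13.1 ± 2.3 to 1.04 ± 0.169 CPM. Macrophage markers had 2 of 15 higher, 2 lower and 11 not passing (0.723); the iron exporter gene Slc40a1 fell by 1.45 ± 0.10. With fry, 5 of these lists passed as lower: megakaryocyte (adjusted p = 0.00215), dendritic cell (0.00578), stromal (0.00723), mast cell (0.0123) and T cell (0.0153). Over their alternatives the adjusted p of these 5 reached 0.698 to 0.84. Only 4 B cell and plasma cell markers could be tested, fewer than the 5 that a list needed; 0 were higher and 1 lower over all genes, and 0 in either direction adjusted over the list alone.

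The lists for RNA and sample handling did not pass. Immediate-early genes had 3 of 17 higher, 5 lower and 9 not passing, also when adjusted over the list alone (camera adjusted p = 0.723). Dusp1, an inducible phosphatase gene, rose from 3.31 ± 0.187 to 6.29 ± 1.31 CPM, and Btg2 fell. Mitochondrially encoded genes had 4 of 13 higher, 1 lower and 8 not passing (4 and 2 adjusted over the list alone, camera adjusted p = 0.723), with mt-Co1 at 8590 ± 342 and 9720 ± 225 CPM. Camera's direction turned to lower without resistant library 1 (0.981). The sign of the median, the mean and the test differed in 5 lists, 1 of them the MLL-AF9 list. The immediate-early list tested lower with a positive median (0.04), the mitochondrially encoded list tested higher with a negative median (-0.01). The anthracycline (mean -0.26) and NRF2 (mean -0.05) lists tested higher with negative means. The direction of the anthracycline list turned to lower without sensitive library 2 or 3 (adjusted p = 0.876 and 0.994), and that of the pro-apoptotic list to higher without sensitive library 3 or resistant library 1 (0.92 and 0.959).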

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

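Removal of the transcript length or GC trend before camera was chosen only after the results were seen; the other alternatives were planned. Of the 174 named genes that could be tested, 162 passed the edgeR test, and over 15 alternatives 16 of the 174 lost a call, 5 gained one and 0 changed direction. Counts of genes higher and lower stayed within 1.5 times of 2475 and 2785 with RLE (2553 and 2718), upper quartile (2515 and 2734), DESeq2 (2384 and 2553), limma-voom (2487 and 2823), no low-count filter (2549 and 2933), a CPM filter (2463 and 2606) and other cell type genes left out (2462 and 2768). DESeq2 shared 4745 of its calls with the edgeR test and limma-voom 5195. With library totals alone, 2087 genes were higher and 3136 lower (40% higher against 47.1%), and the median of all genes shifted by -0.034. A minimum fold change of 1.5 (glmTreat) left 308 higher and 542 lower, and an adjusted p under 0.01 left 1408 and 1726, as stricter criteria must lower the counts. Leaving out 1 library gave 1641 to 2521 higher and 2015 to 2711 lower genes, the lowest without sensitive library 2, with fewer samples per fit. Lists called were then 3 to 4 higher and 4 to 6 lower. Depth limits the genes near the floor of 3 counts, such as Tcf19, Zcchc3, Myef2 and Nqo1 in resistant libraries and Npr3 in sensitive ones.

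Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at 0.037, -0.006 and -0.086, and not every library correlated best with its own number. With the replicate number as a block, 2497 genes were higher and 2824 lower, 5034 of these 5321 calls shared, and 3 lists were higher and 5 lower.

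The lists called, 3 higher and 5 lower, of which 1 lower list was of another cell type, moved most with the list test. With an estimated correlation 0 were higher and 0 lower, 0 of them of another cell type. The estimated correlations of the called lists ran from 0.042 (niche adhesion) to 0.496 (erythroid), against the preset 0.01. The estimated setting also takes camera's degrees of freedom from the libraries, not the genes. How much of the loss came from the correlations and how much from this was not tested. With fry 5 were higher and 15 lower, 6 of them of other cell types, and the MLL-AF9 list turned to lower (0.0413). Without the low-count filter, which adds genes, 8 lists were lower, 2 of other cell types. Of 18 changes of direction, 17 were of lists that passed in neither fit, and the cause was not tested. These were the pro-apoptotic list with limma-voom (0.959), a CPM filter (0.84) and the GC trend removed (0.821), the macrophage list with a CPM filter (0.829), the anthracycline and stem cell lists without a low-count filter (both 0.905), and the mitochondrially encoded list with the length (0.758) or GC (0.755) trend removed. The others arose on leaving out 1 library, where adjusted p ranged from 0.8 to 0.959 for the pro-apoptotic list, 0.772 to 0.994 for anthracycline, 0.341 to 0.959 for S phase, 0.361 to 0.928 for interferon, 0.474 to 0.78 for glycolysis and 0.385 to 0.981 for mitochondrially encoded genes.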

Other observations

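The tests of carry-over of neutrophils or erythroid cells, of whole chromosomes and of leukemia clones were chosen only after the results were seen. The bounds of the erythroid and muscle tests were made to include the spread of their genes after their values were known. Under the bounds first set, the erythroid test had come out against carry-over and the muscle test against a wider fall. The genes named in this part, other than Padi4, Ngp and the globins, lie outside the rule for named genes and were chosen after the data were seen.

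Several strongly changed genes belong to none of the lists. The RNA-binding protein gene Lin28b, known to block maturation of let-7 microRNAs, rose 7.17-fold in resistant blasts, from 12.2 ± 1.73 to 87.6 ± 8.31 CPM (SD, n = 3 per group; edgeR adjusted p = 7.47e-08). The Notch ligand gene Jag1 rose by 2.95 ± 0.25 on the log2 scale, the phosphodiesterase gene Pde4d by 1.69 and the deubiquitinase gene Usp47 by 1.11. The chromatin organiser gene Satb1 had a log2 fold change of -4.49, the cathepsin gene Ctsc, which activates granule proteases, one of -4.91, and Cmah, a sialic acid hydroxylase gene, one of -1.62. The muscle regulator genes Myog and Mymk had 251 and 78 counts in sensitive libraries and 0 in resistant ones, at least 79.2-fold and 24.6-fold lower against a floor of 3 counts per group. The muscle troponin gene Tnnt1 fell from 51.2 ± 4.27 to 14.6 ± 1.03 CPM, the muscle tropomyosin gene Tpm2 from 4.03 ± 1.55 to 0.209 ± 0.13 CPM and the acetylcholine receptor gene Chrnd from 1.84 ± 0.348 to 0.0282 ± 0.0246 CPM. The resistant value of Chrnd rests on 2 counts in sum.

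Expression of Xist was at most 0.157 CPM in all 6 libraries, and that of the Y-linked gene Ddx3y was 81.4 to 107 CPM.

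Ribosomal protein, oxidative phosphorylation and MYC target genes rose by a pooled median of 0.189 on the log2 scale (122 genes). A bias of short transcripts would need this to vanish once the trend with transcript length is removed, but the median was 0.167 (95% bootstrap interval over genes 0.152 to 0.186), and 0.217 (0.197 to 0.236) with the GC trend removed. These intervals resample the genes as independent, so they do not cover the spread between libraries. A trend with expression level could account for part of the rise, since 10000 random lists matched on mean expression had a median of 0.065. It leaves the rest unexplained, as the pooled median of 0.189 lay at percentile 100 of these random lists, whose highest median was 0.162. Like the bootstrap, this comparison treats genes as independent and does not cover the spread between libraries. These trends thus do not account for the whole rise, though the lists did not pass with an estimated correlation. Reads shared with ribosomal protein pseudogenes, drug exposure and resistance itself stay open and untested as separate sources.

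Neutrophil maturation genes and erythroid markers were both lower in resistant blasts, which normal cells in the sensitive libraries could produce, and the labels name no sort that would remove them. The abundant neutrophil transcripts S100a8, S100a9, Camp, Ltf, Ngp and Lcn2 together had a fall in CPM 1.42 times that of Padi4 (75.9 CPM), which lies between the value set for carry-over (10 times or more) and that set against it. These 6 genes are also in the neutrophil maturation list, and myeloid blasts can express them, with sensitive means of 5.27 CPM (Camp) to 44.2 CPM (Ngp). The 4 globins were the most abundant erythroid markers, but the other 7 had a median of -0.47 with a median absolute deviation of 1.51, as Slc4a1 (-6.83) and Alas2 (-4.57) were lower and Trim10 (1.90) higher. The neutrophil value fell between its bounds, and the erythroid median did so only after the spread was added to its bound. Carry-over and a lower maturation of the blasts therefore cannot be told apart here.

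Because Myog and Mymk act in muscle development, further muscle genes might have fallen with them. The list of 70 muscle genes left out those already seen to fall, among them Myog, Mymk, Tnnt1, Tpm2 and Chrnd. Of these 70, 26 were tested, 4 were higher and 7 lower, with a median of -0.03 and a median absolute deviation of 0.84. With members changed both ways and the genes seen to fall left out, this neither shows a wider fall nor excludes one in some members.

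Higher Lin28b might lower let-7 activity and so raise genes with let-7 sites. The 447 tested genes with a let-7 8mer in the 3′ UTR had a median log2 fold change of -0.01, that is 0.001 below the 8618 genes without a 6mer, and this difference lay at percentile 78 of 200 control 8mers of the same bases. Such a rise was not seen, and the let-7 target genes Hmga2 (-0.24 ± 0.13, edgeR adjusted p = 0.191) and Igf2bp2 (0.16 ± 0.11, 0.298) did not pass.

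The real split of the 6 libraries gave 5260 changed genes, and the highest of the other splits gave 1. Only 1 of 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. Gain or loss of whole chromosomes could change many genes at once, but no autosome's median log2 fold change exceeded 0.048 in size, which argues against it. Whether the groups are different leukemia clones stays open: the coefficient of variation of 8.4% within groups does not name clones, so clone and treatment cannot be told apart.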
